A study of Liolophura hirtosa with 16 samples.

How the data were processed

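Single-colour arrays were hybridised with Cy5-labelled RNA from 3 sections of the chiton radula and from foot muscle. Per the labels' protocols, RNA was extracted with Trizol and labelled with the Kreatech ampULSe kit, and the series' design text states 12 animals, pools of 3 animals and 4 pools per tissue. Groups and replicate numbers were taken from the sample titles. The pools of one tissue held different animals as far as the design text tells, and whether pools of the same number held the same animals in each tissue was not stated in the sources used here. Sampling, sectioning and pooling were done by the authors, and the p-values measure the spread between arrays recorded as the same tissue. With the files as recorded, that spread includes arrays whose identity is in doubt, as described below. It need not be a spread between pools alone.

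Each array had 1 scanner table. Per the file headers, it held the mean and the median foreground pixel intensity of each spot on a linear scale, with no background column, control spot or detection flag, and with every spot marked as included. The extraction software was not given in the sources used here. Each of the 2240 probes had 1 spot. They covered 493 sequences, with 5 probes on 334, 4 on 122, 3 on 15, 2 on 15 and 1 on 7 of them, and the median sequence length was 606 nt. Each array filled 1 of 4 sectors of a slide, and the 4 arrays of each tissue lay in 4 different sectors. Which arrays shared a slide was not given in the sources used here. The mean foreground was at the scanner maximum of 65535 in 14 spot values, all on 2 probes of Contig[0011], which were kept. Without background measurements, no probe could be called above or below background, so that differences between dim values understate the change in RNA by an unknown amount.

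The authors also deposited a value table, whose values were a ratio. Set against the scanner tables, each column was the mean foreground of a probe divided by the mean over all probes of an array, on a linear scale, with no background correction and no centring of probes. Column means were 1 and column medians lay between 0.247 and 0.457. The scale and direction were thereby recovered from the values. The SD of the log2 ratio between a column and its own scanner file was at most 9.65e-05 for 12 arrays. For immature and calcium replicates 2 and 4 it was 0.860 and 0.931, and these columns matched the files of each other's tissue with the same replicate number. The scanner file recorded for each sample was used throughout, as fixed before the data were examined. Fits with the 4 arrays left out and with the files assigned as in the value table were chosen after seeing the data.

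Mean foreground intensities were corrected with normexp (offset 50), log2-transformed and quantile-normalized between arrays in R 4.3.3 with limma 3.58.1. A linear model with a mean per tissue was fitted over all 16 arrays, so that tissues shared one estimate of the spread, and tested with eBayes (two-sided). Comparisons were the 3 pairs of sections, each section against foot muscle, the mean of the 3 sections against foot muscle, and a moderated F-test for any difference among the 3 sections. Benjamini-Hochberg adjustment was made within each comparison, and probes with an adjusted p under 0.05 are called. Probes of a sequence were tested singly. Their mean levels differed by a median of 1.77 on the log2 scale within a sequence, so that no probe's level was set against another's.

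Probes to be named were fixed by a rule before the data were examined: called probes whose arrays of one tissue all lay above those of the other, largest difference first, 1 probe per sequence. Because the files gave no gene names, at most 2 probes per direction and comparison are named. For the same reason, keyword lists of genes for iron handling, muscle, chitin, mineral handling and other functions, and of cell type markers, matched 0 probes, and their set tests were not run.

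On simulated changes among the 2240 probes for iron against immature teeth, the fit recovered 34% of probes changed by 0.5 on the log2 scale, 84% of those changed by 1, 94% by 2 and 96% by 3 with the files as recorded, and called 0.392% of unchanged probes. With the value table's assignment it recovered 54%, 92%, 100% and 100%, and called 0.490% of unchanged probes. The changed probes were drawn at random and the noise was independent. The recovery as recorded is thus an average that does not carry over to probes with a wide spread within immature and calcium arrays. In the data, calls above 2-fold numbered 92 higher and 9 lower as recorded, against 150 and 125 with the value table's assignment.

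Whether replicate numbers pair the arrays was checked by the correlation across probes of deviations from the tissue means between arrays of the same number. The required minimum of 0.1 in each of the 4 pairs was met, with files as recorded, for immature and iron (0.167 to 0.344), iron and foot muscle (0.112 to 0.569) and calcium and foot muscle (0.111 to 0.328). It was not met for immature and calcium (-0.892 to -0.674), immature and foot muscle (lowest -0.03) or iron and calcium (lowest 0.09). These values rest on tissue means that include the disputed arrays, so a miss as recorded does not show that the numbers fail to pair. With the value table's assignment, the minimum was met for iron and calcium (0.543 to 0.694) and immature and foot muscle (0.241 to 0.437). It was met too for immature and iron (0.155 to 0.688) and iron and foot muscle. It was missed for immature and calcium (lowest -0.222) and calcium and foot muscle (lowest 0.0170). The pairing thus comes from the values and not from the design.

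Alternatives tried were no background correction, normexp with offset 16, the median in place of the mean pixel intensity, median, 75th percentile and cyclic loess scaling, leaving out the dimmest 25% of probes, log2 of the deposited value table, only the tissues compared, the replicate number or the sector as a block, array weights, an intensity-dependent and robust variance prior, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.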

Results

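Gene expression was measured along the radula of the chiton Acanthopleura hirtosa, listed in the labels as Liolophura hirtosa, and in its foot muscle. Chitons are marine molluscs that graze on rock with the radula, a ribbon of tooth rows that forms continuously at one end, so that successive rows along it are successive stages of tooth mineralization. Each radula was dissected into a section with immature teeth, a section with iron-deposited teeth and a section with calcium-deposited teeth, and foot muscle of the same animals served as a tissue outside the radula. RNA of 12 wild adult animals was pooled in equal parts from 3 animals per pool, which gave 4 pools and 4 single-colour arrays for each of the 4 tissues, 16 arrays in all. Each array carried 2240 probes of 35 to 40 nt on 493 chiton sequences, of which 109 were named as contigs and 384 by clone plate and well. The files paired no probe with a gene name, so that probes are given by their sequence name and position, and positions are bases within that sequence and not places in a genome. The median foreground intensity of an array lay between 200.1 and 426 units, and 0 to 2 probes per array were at the scanner maximum. With 4 arrays per tissue, the number of arrays limited the precision of every value.

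The deposited sources disagreed on the identity of 4 arrays. The column of the authors' value table for immature replicate 2 was a constant multiple of the scanner file recorded for calcium replicate 2, and the reverse, and the same held for replicate 4 of these tissues, whereas the other 12 columns matched their own files. The labels do not say which source is right, and the correlations between arrays that bear on it follow. Values are therefore given with the scanner files as recorded, and beside them with the 4 disputed arrays left out (the undisputed arrays, n = 2 for immature and calcium, n = 4 for iron and foot muscle) and with the files assigned as in the value table (n = 4 for each tissue). Means of iron and of foot muscle, and the mean of the 3 sections, were the same under both assignments, and only their errors differed.

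Iron arrays and foot muscle arrays correlated more closely within their own tissue than with any other tissue. Across probes, which are not independent replicates, the 4 iron arrays correlated with each other at a Pearson r of 0.961 to 0.983 and the 4 foot muscle arrays at 0.955 to 0.983. With the files as recorded, arrays of the immature section correlated at 0.760 to 0.971 and those of the calcium section at 0.734 to 0.989, whereas arrays of the one section correlated with those of the other at a median of 0.874. Each disputed array correlated at 0.734 to 0.789 with the undisputed arrays of its recorded section and at 0.950 to 0.987 with those of the other section. With the value table's assignment, the ranges were 0.966 to 0.989 within the immature and 0.945 to 0.987 within the calcium section. Among the undisputed arrays, immature and calcium were the pair of sections least alike, at a median r of 0.763. The median was 0.809 for immature and iron and 0.864 for iron and calcium. Foot muscle had a median r of 0.828 with calcium, 0.741 with iron and 0.711 with immature arrays.

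**Figure D1:**
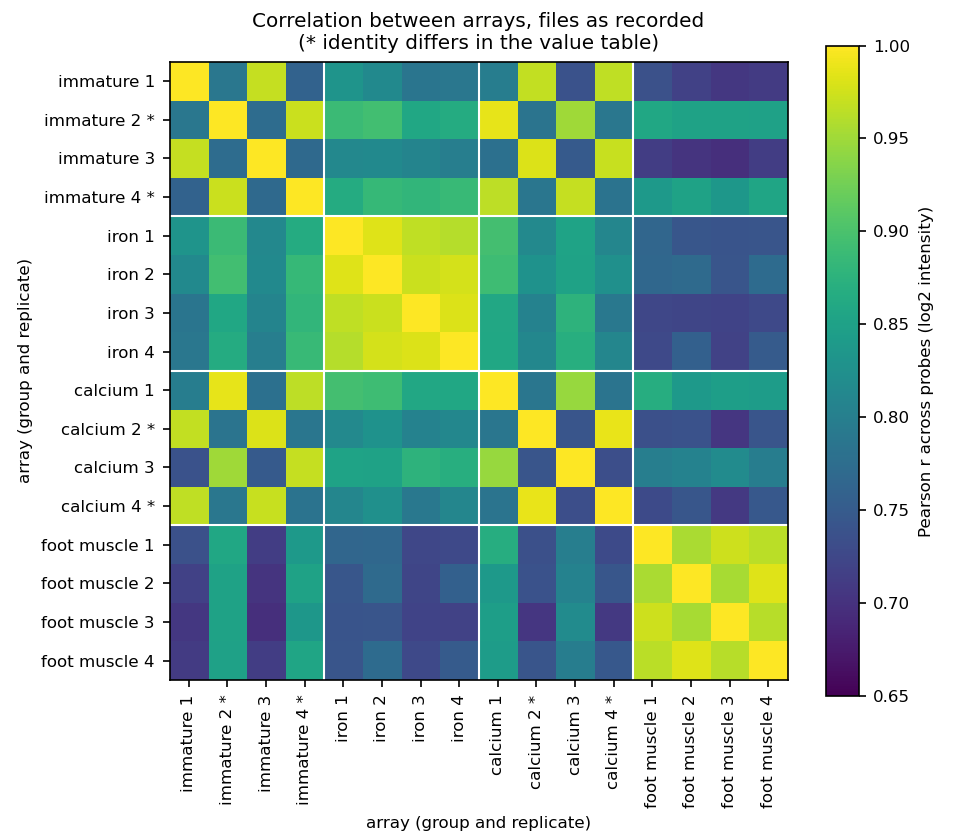
Pearson r between the 16 arrays across 2240 probes on log2 normalized intensity, with files as recorded; both axes list the arrays by tissue and replicate, the colour gives r, and asterisks mark the 4 arrays whose identity differs in the value table. The iron block lies at 0.961 or above, whereas the immature and calcium blocks hold values down to 0.760 and 0.734.

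The comparison of iron-deposited with immature teeth asked which transcripts changed as mineral first entered the teeth. Contig[0058] and the clone PlateD-G3-5-SMART had the largest rises as recorded among probes that met the naming rule. That ranking includes the disputed arrays. PlateD-E11-5-SMART at bases 246 to 282 did not meet the rule as recorded. Among the undisputed arrays it rose from 7.96 in immature to 12.07 in iron, more than Contig[0058] did. On Contig[0058], the probe at bases 249 to 283 (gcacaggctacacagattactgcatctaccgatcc) had a log2 intensity of 14.37 ± 0.11 (SD, n = 4) in iron and 10.21 ± 2.0 (SD, n = 4) in arrays recorded as immature, a 17.9-fold difference (log2 4.16, SE 0.89, limma adjusted p = 0.00801). It was 5.57-fold higher in iron among the undisputed arrays (immature 11.88 ± 0.17, SD, n = 2; limma adjusted p = 3.31e-08) and 5.74-fold higher with the value table's assignment. All 5 probes on Contig[0058] were called higher in each of these fits. On PlateD-G3-5-SMART, the probe at bases 577 to 611 (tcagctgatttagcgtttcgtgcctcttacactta) was 16.3-fold higher with the files as recorded (log2 4.03, SE 0.85, limma adjusted p = 0.00734) and 50.8-fold higher among the undisputed arrays, and again all 5 probes of its sequence were called.

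On Contig[0097] and Contig[0129], 3 of 5 probes each were called lower in iron-deposited than in immature teeth as recorded, and all 5 among the undisputed arrays. Contig[0010] at bases 1258 to 1292 and Contig[0054] at bases 153 to 187 did not meet the naming rule as recorded. Among the undisputed arrays both fell further than the probes named here. Contig[0010] went from 15.79 in immature to 9.04 in iron, and Contig[0054] from 14.13 to near its level in foot muscle. On Contig[0097], the probe at bases 237 to 272 (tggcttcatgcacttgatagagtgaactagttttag) was 3.11-fold lower in iron as recorded (log2 -1.64, SE 0.38, limma adjusted p = 0.013) and 4.71-fold lower among the undisputed arrays, and under loess scaling the call as recorded ended (log2 -1.575, limma adjusted p = 0.0832). The probe at bases 245 to 282 of Contig[0129] (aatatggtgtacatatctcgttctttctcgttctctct) was 2.83-fold lower as recorded, with a limma adjusted p of 0.0457, and 4.80-fold lower among the undisputed arrays, with a limma adjusted p of 2.26e-05. As recorded, the call on Contig[0129] ended in 17 of 31 alternative settings, its log2 difference staying between -2.26 and -1.23. Over all probes, limma called 170 at an adjusted p under 0.05 with the files as recorded, 143 higher and 27 lower in iron. Those lower numbered 12 to 39 with 1 array left out, 56 with array weights, and 15 under median scaling and 15 with the sector as a block. It called 431 among the undisputed arrays (236 higher, 195 lower) and 511 with the value table's assignment (288 higher, 223 lower). All 170 were among the 511, in the same direction, and 424 of the 431 were.

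The comparison of calcium-deposited with immature teeth spanned the earliest and latest sections, and its outcome rested on the 4 disputed arrays. With the files as recorded, limma called 0 probes, and 1 probe had an unadjusted p under 0.05 where chance gives 112. The undisputed arrays gave 429 calls (217 higher, 212 lower in calcium) and the value table's assignment 622 (361 higher, 261 lower), which held all 429 in the same direction. Cyclic loess scaling turned the balance to 150 higher and 232 lower among the undisputed arrays and to 248 higher and 308 lower with the value table's assignment. Probes were named here by the same rule on the value table's assignment, because none passed with the files as recorded.

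Contig[0010] and Contig[0054] were bright in undisputed immature arrays and near the level of foot muscle in both iron and calcium arrays. On Contig[0010], the probe at bases 1258 to 1292 (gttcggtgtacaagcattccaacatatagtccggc) had a log2 intensity of 15.79 in both undisputed immature arrays, 8.98 ± 0.65 (SD, n = 2) in calcium and 8.13 ± 0.65 (SD, n = 4) in foot muscle. It was 112-fold lower in calcium than in immature arrays (log2 -6.81, SE 0.48, limma adjusted p = 1.62e-07), and all 5 probes of the sequence were called lower. With the files as recorded, its log2 difference was 0.25 with an SE of 1.89. On Contig[0054], the probe at bases 153 to 187 (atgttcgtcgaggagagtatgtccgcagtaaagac) was 96.3-fold lower among the undisputed arrays (log2 -6.59, SE 0.21, limma adjusted p = 3.32e-10), and as recorded its log2 difference was 0.17 with an SE of 1.79. Quantile scaling gives arrays that share a rank the same value, so a spread of 0 between arrays means an equal rank.

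Contig[0288] and PlateD-E11-5-SMART were higher in calcium than in immature arrays. PlateD-E11-5-SMART at bases 246 to 282 was already at 12.07 in iron arrays, against 7.96 in undisputed immature and 12.74 in undisputed calcium arrays. Contig[0288] at bases 281 to 315 had 9.34 in iron arrays. On Contig[0288], the probe at bases 281 to 315 (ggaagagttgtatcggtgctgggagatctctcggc) had a log2 intensity of 13.14 ± 0.32 (SD, n = 2) in calcium against 7.90 ± 0.06 (SD, n = 2) in immature undisputed arrays, a 38.0-fold difference with a limma adjusted p of 8.01e-09. All 4 probes of the sequence were called higher. The probe at bases 246 to 282 of PlateD-E11-5-SMART (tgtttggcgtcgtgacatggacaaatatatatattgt) was 27.4-fold higher among the undisputed arrays (log2 4.77, SE 0.17, limma adjusted p = 5.75e-10). With the files as recorded, the log2 differences of these probes were -0.08 with an SE of 1.42 and -0.09 with an SE of 1.30.

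**Figure D2:**
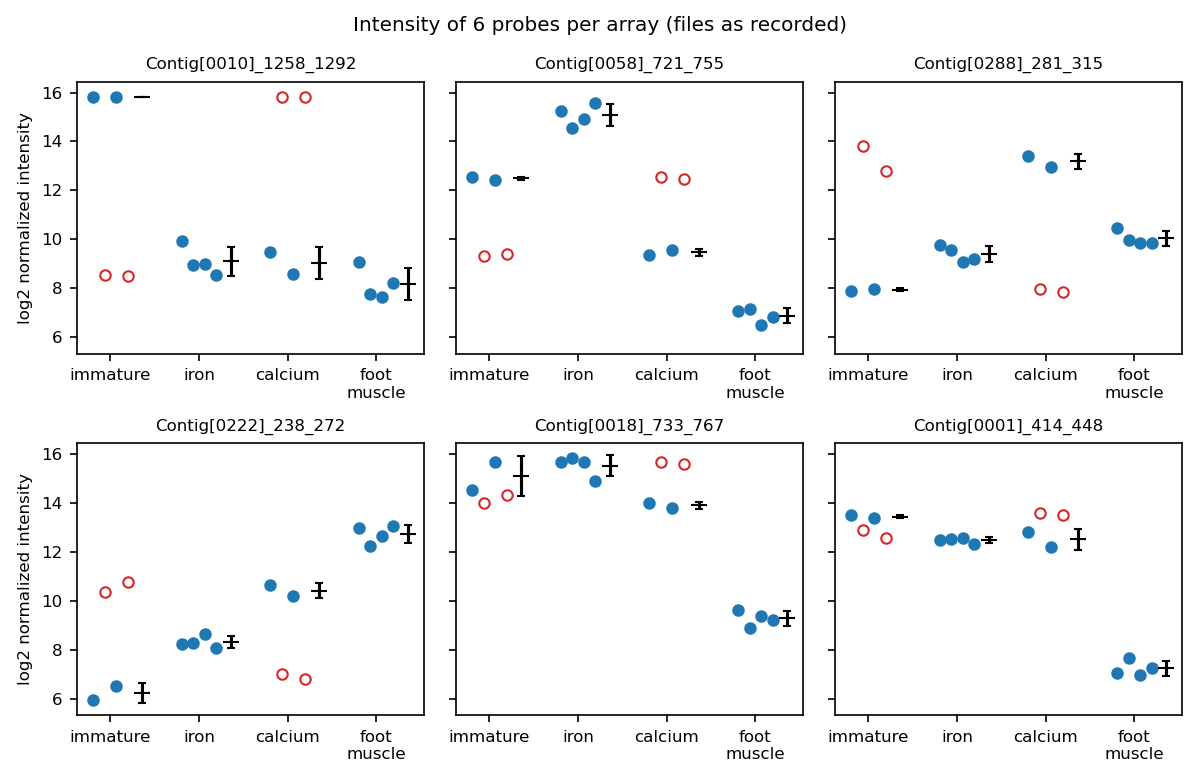
Log2 normalized intensity (vertical axes) of 6 probes in each array by tissue (horizontal axes), with files as recorded; filled points are undisputed arrays, open red points the 4 disputed ones, and the black bar is the mean ± SD of the undisputed arrays. The probe on Contig[0010] lies at 15.8 in the undisputed immature arrays, and the 2 disputed arrays recorded as calcium lie at that level too.

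The comparison of calcium-deposited with iron-deposited teeth followed the teeth from iron to calcium deposition. Contig[0058], which had risen in iron, was lower again in calcium, by 18.7-fold as recorded (log2 -4.23, SE 0.89, limma adjusted p = 0.00785) and by 59.4-fold among the undisputed arrays at the probe at bases 249 to 283. On Contig[0267], the probe at bases 305 to 339 (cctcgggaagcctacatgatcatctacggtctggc) was 17.1-fold lower as recorded (log2 -4.09, SE 0.80, limma adjusted p = 0.00549) and 43.7-fold lower among the undisputed arrays. All 5 probes of Contig[0058] and all 5 of Contig[0267] were called lower in each fit. Contig[0097] was 3.24-fold higher in calcium at bases 237 to 272 as recorded (limma adjusted p = 0.0113) and 2.01-fold higher among the undisputed arrays, and under loess scaling this call as recorded ended too (log2 1.62, limma adjusted p = 0.0722); 3 of its 5 probes were called higher in each fit. On Contig[0110], the probe at bases 53 to 87 (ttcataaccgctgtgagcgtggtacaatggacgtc) was 2.68-fold higher as recorded and 1.80-fold higher among the undisputed arrays, with limma adjusted p values of 0.0363 and 0.00591, and 1 and 2 of the 4 probes of its sequence were called. As recorded, the call on Contig[0110] ended in 13 of 31 alternative settings, its log2 difference staying between 0.57 and 1.89.

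Limma called 172 probes between calcium and iron as recorded (21 higher, 151 lower in calcium), 389 among the undisputed arrays (205 higher, 184 lower) and 521 with the value table's assignment (281 higher, 240 lower). All 172 were among the 521 in the same direction. As recorded, those higher in calcium numbered 11 to 31 with 1 array left out and 36 under 75th percentile scaling. Without iron replicate 3, the count as recorded was 112, and with array weights it was 528 (231 higher, 297 lower). The log2 values of the deposited table gave 331 (160 higher, 171 lower). Loess scaling gave 143 higher and 195 lower among the undisputed arrays. It gave 156 higher and 271 lower with the value table's assignment, and median scaling 184 higher and 238 lower.

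Taken over the 3 sections at once, limma's moderated F-test called 159 probes on 60 sequences as recorded, 592 probes on 196 sequences among the undisputed arrays and 740 probes on 238 sequences with the value table's assignment. Without iron replicate 3 the count as recorded was 99, and with array weights 448. As recorded, 140 of the 159 called probes were highest in iron, 11 in immature and 8 in calcium. Calcium against immature had 0 calls as recorded, so the calls there mostly reflect iron against the other sections. The 140 therefore do not show that iron peaks predominate. Among the undisputed arrays, 191 of the called probes were highest in immature, 200 in iron and 201 in calcium teeth. Of the 191 that peaked in immature teeth, 160 were also called higher there than in foot muscle and 3 lower, and of the 200 that peaked in iron-deposited teeth, 171 were called higher and 4 lower. Of the 201 that peaked in calcium-deposited teeth, 81 were called higher than foot muscle and 34 lower.

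The comparisons with foot muscle asked which transcripts distinguished radula tissue from a tissue that forms no teeth. Contig[0018] and Contig[0001] were high in all 3 sections. On Contig[0018], the probe at bases 733 to 767 (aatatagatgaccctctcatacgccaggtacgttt) was 52.0-fold higher in the mean of the sections than in foot muscle (log2 5.70, SE 0.36, limma adjusted p = 3.01e-08), and that at bases 414 to 448 of Contig[0001] (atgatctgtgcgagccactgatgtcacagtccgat) was 49.5-fold higher (log2 5.63, SE 0.23, limma adjusted p = 4.85e-10). Contig[0222] and Contig[0113] were high in foot muscle. The probe at bases 238 to 272 of Contig[0222] (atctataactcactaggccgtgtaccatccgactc) was 19.5-fold lower in the radula mean (log2 -4.29, SE 0.86, limma adjusted p = 0.00209), and that at bases 49 to 83 of Contig[0113] (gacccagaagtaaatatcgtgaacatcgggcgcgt) was 11.7-fold lower (log2 -3.55, SE 0.55, limma adjusted p = 0.000271). Every probe on these 4 sequences was called in the same direction. All 12 radula arrays lay on one side of all 4 foot muscle arrays at these 4 probes. Limma called 597 probes (204 higher, 393 lower in the radula mean) as recorded, 819 (330 higher, 489 lower) among the undisputed arrays and 860 (344 higher, 516 lower) with the value table's assignment, which held all 597 in the same direction.

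Of the 3 sections, iron-deposited teeth had the most calls against foot muscle under quantile scaling in each of the 3 full sets of arrays. The sections were not on an equal footing, since the undisputed arrays held n = 4 for iron and n = 2 for the others. Calls above 2-fold there were 208 higher and 122 lower for iron, and 225 and 126 for immature teeth. They were 211 and 122 against 218 and 119 with the value table's assignment, and 182 and 112 against 96 and 64 as recorded. With 1 array left out under the value table's assignment, the ranges overlapped, at 735 to 898 for iron and 687 to 795 for immature teeth. With the log2 values of the deposited table, iron-deposited teeth had 368 and immature teeth 397. Neither iron nor foot muscle held a disputed array. On Contig[0058], the probe at bases 721 to 755 (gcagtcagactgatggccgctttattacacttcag) had a log2 intensity of 15.07 ± 0.45 (SD, n = 4) in iron and 6.88 ± 0.29 (SD, n = 4) in foot muscle, a 291-fold difference (log2 8.19, SE 0.84, limma adjusted p = 4.86e-06). On Contig[0018], the probe at bases 523 to 557 (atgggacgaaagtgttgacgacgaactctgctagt) was 80.5-fold higher in iron (14.16 ± 0.13 against 7.83 ± 0.35, SD, n = 4; limma adjusted p = 1.34e-08). Contig[0222] at bases 238 to 272 was 21.5-fold lower in iron (8.31 ± 0.25 against 12.74 ± 0.37, SD, n = 4; limma adjusted p = 0.00587). On Plate-C-F10-5-SMART, the probe at bases 57 to 91 (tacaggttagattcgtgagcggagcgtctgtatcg) was 15.1-fold lower (8.98 ± 0.30 against 12.90 ± 0.13, SD, n = 4; limma adjusted p = 0.00478). Limma called 633 probes (252 higher, 381 lower in iron) as recorded, 801 among the undisputed arrays and 847 with the value table's assignment. Between 633 and 847, the values of iron and foot muscle are unchanged, and the counts differ because all tissues share one estimate of the spread. For Contig[0058] at bases 721 to 755, the SE was 0.84 as recorded and 0.18 with the value table's assignment.

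Contig[0001] and Contig[0018] met the naming rule for immature teeth against foot muscle with the files as recorded. At bases 414 to 448 Contig[0001] was 58.0-fold higher as recorded (log2 5.86, SE 0.28, limma adjusted p = 4.7e-09) and 73.2-fold higher among the undisputed arrays, and Contig[0018] at bases 733 to 767 was 41.1-fold and 58.2-fold higher. Contig[0222] at bases 238 to 272 was 20.3-fold lower as recorded (limma adjusted p = 0.0129) and 86.8-fold lower among the undisputed arrays, and Contig[0113] at bases 49 to 83 was 13.0-fold and 27.4-fold lower. Limma called 301 probes as recorded (108 higher, 193 lower in immature teeth; 124 to 249 lower with 1 array left out), 648 among the undisputed arrays (281 higher, 367 lower) and 759 with the value table's assignment (305 higher, 454 lower).

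In calcium-deposited teeth, Contig[0001] at bases 414 to 448 was 55.4-fold higher than in foot muscle as recorded (log2 5.79, SE 0.28, limma adjusted p = 5.52e-09) and 37.6-fold higher among the undisputed arrays. Contig[0018] at bases 733 to 767 was 45.1-fold and 24.9-fold higher. Contig[0222] at bases 238 to 272 was 17.0-fold lower as recorded (limma adjusted p = 0.0176) and 4.96-fold lower among the undisputed arrays. As recorded, this call ended without calcium 2 or 4 and under median scaling (limma adjusted p = 0.0562, 0.0569 and 0.0638). Contig[0113] at bases 49 to 83 was 14.2-fold and 5.39-fold lower. Limma called 313 probes as recorded (110 higher, 203 lower in calcium teeth), and 492 (121 higher, 371 lower) with the replicate number as a block and 802 (295 higher, 507 lower) with array weights. With only the tissues compared, 96 were higher and 116 lower. It called 438 among the undisputed arrays (197 higher, 241 lower) and 511 with the value table's assignment (218 higher, 293 lower).

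**Figure D3:**
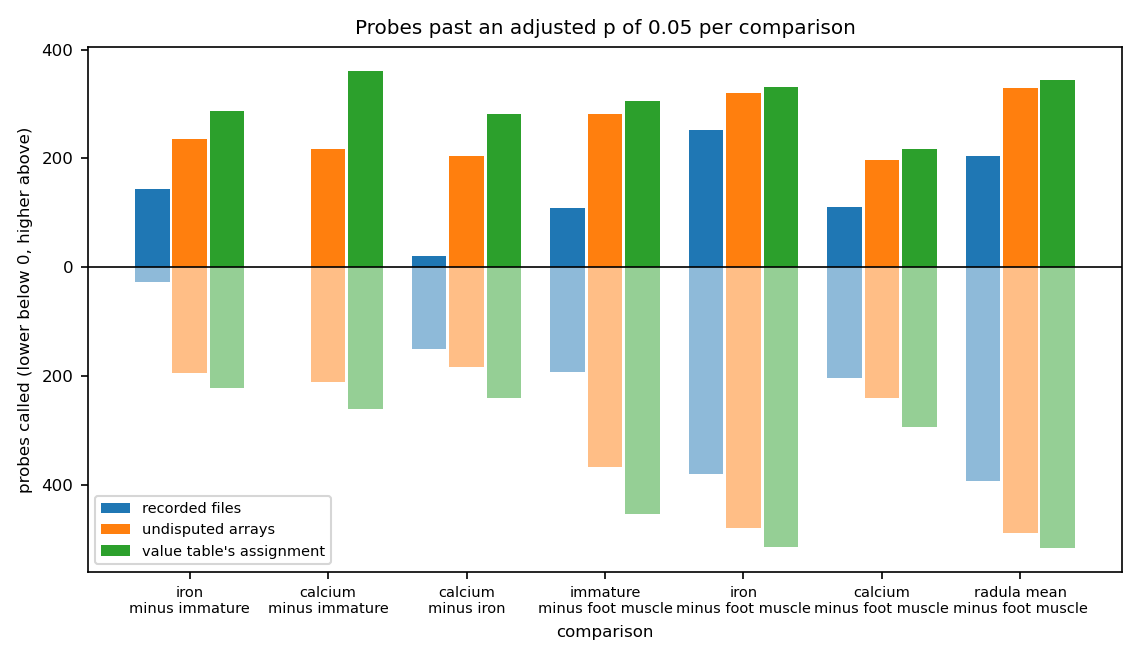
Number of probes past a limma adjusted p of 0.05 in 7 comparisons (horizontal axis), with those higher in the first-named tissue above 0 and those lower below 0 on the vertical axis; colours are the files as recorded, the undisputed arrays and the value table's assignment. Calcium minus immature has 0 calls with files as recorded and 429 and 622 in the other fits.

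The balance of higher and lower calls against foot muscle depended on the scaling between arrays. For the radula mean with files as recorded, median scaling gave 217 higher and 209 lower, cyclic loess 226 and 110, and scaling to the 75th percentile 175 and 1131. The log2 values of the deposited table, which differ in the 4 disputed arrays and in having no background correction as well, gave 220 and 138. The median of all probes had a log2 of -0.11 under quantile scaling and of -0.17, -0.000757 and -0.47 under median, loess and 75th percentile scaling. Higher and lower calls as recorded were 100 and 54, 104 and 48, and 100 and 294 for immature teeth under these 3 scalings. They were 281 and 235, 287 and 117, and 227 and 1217 for iron, and 116 and 55, 114 and 55, and 109 and 658 for calcium. For the radula mean, the undisputed arrays gave 368 and 244, 401 and 150, and 274 and 1065, and the value table's assignment 376 and 323, 415 and 164, and 284 and 1323. The named probes kept their direction under each of these scalings. With the slide sector as a block and files as recorded, limma called 134 probes for iron against immature, 0 for calcium against immature and 142 for calcium against iron. It called 238, 569 and 250 for immature, iron and calcium against foot muscle, 540 for the radula mean and 130 for any difference among sections. A sector held 1 array of each tissue, so that no test within a sector was possible.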

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

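The tests of an exchange of files, of differences between pools and of the choice of scaling were chosen only after the results were seen, as were the fits on the value table's assignment and the splits that keep to replicate numbers or part all pairs. Of 76 sets of 4 arrays, 68 for the named probes and 8 for the median and 75th percentile of array intensity, 5 had an array far from the other 3, where chance gives about 1 in 20. On Contig[0058] at bases 249 to 283, iron replicate 1 had a log2 intensity of 14.54, whereas the other 3 iron arrays shared a rank at 14.32. The same probe had 7.31 in foot muscle replicate 3 against 7.64 to 7.68 in the others. Contig[0288] at bases 281 to 315 had 10.47 in foot muscle replicate 1 against 9.86 to 9.96. Contig[0054] at bases 153 to 187 had 7.71 in foot muscle replicate 1 against 7.41 to 7.46. Contig[0018] at bases 733 to 767 had 14.91 in iron replicate 4 against 15.69 to 15.82.

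Immature and calcium replicates 2 and 4 stood apart from the other arrays of their recorded tissue. Pools that differ this much within a tissue were argued against, because the lowest r of these arrays with the undisputed arrays of the other tissue was 0.950, above the highest r of 0.896 that any iron array had with the same arrays. An effect of even against odd sectors was argued against too, because such splits called 0 probes within iron and within foot muscle. The 857 that they called within immature and calcium restate the pattern, since the even sectors there held exactly the disputed arrays. A common effect fitted over iron and foot muscle called 92, where sector parity follows replicate number, and one over immature and calcium called 0. A candidate explanation is an exchange of the scanner files between the tissues, since 4 of the 4 arrays lay closer to both undisputed arrays of the other tissue than to either of their own and the authors' value table pairs them that way. The values thus speak against the files as recorded and go with the table's pairing, as far as the labels of the undisputed arrays, on which both sources agree, are right; where in the work an exchange would have happened stays open.

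Calcium arrays, with the value table's assignment, lay closer to foot muscle (median r 0.845) than iron (0.743) or immature arrays did (0.716). A larger share of transcripts that foot muscle also expresses was predicted to lift probes higher in foot muscle above random lists, and not those lower in it. The 501 probes higher in foot muscle than in iron had a median calcium minus immature log2 difference of 0.138. This lay inside the 0.0730 to 0.147 of 10000 random lists of the same size and level, at percentile 92.9, near the upper bound. Staying within that range was set beforehand as evidence against the explanation. The 326 probes lower in foot muscle had a median of 0.148, at percentile 99.9 of their own random lists (0.0422 to 0.121). Neither part of the prediction was met, the first narrowly. Of the probes higher in foot muscle, 65.7% were higher in calcium than in immature arrays, against 55.2% of those lower in it. With a median so near the bound, the test cannot tell whether the explanation holds. A shift of dim probes by the scaling could not be judged, because the probes higher in foot muscle had no excess for it to account for. Their median above the middle level was 0.159.

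More probes were lower than higher in the radula mean than in foot muscle, 393 against 204 as recorded. Dim probes moved by the quantile scaling were argued against, since 65.6% of calls were lower among probes above the median level and 67.0% among those below it. The choice of scaling may account for the balance, because 2 of 4 scalings gave more lower than higher calls and the others the reverse. The 75th percentile of intensity was 294 to 391 units in foot muscle arrays and 430 to 776 in radula arrays. A difference between the tissues in the number of abundant transcripts was not tested.

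Chance was examined by other splits of the arrays. Of the 35 splits of 8 arrays, 1, the real one, gave a count as large for calcium against iron (172 calls, highest other 0) and immature against foot muscle (301, 0). The replicate numbers missed the required minimum for these tissues only as recorded. With the value table's assignment they pair them (r 0.543 to 0.694 and 0.241 to 0.437). As in the comparisons that follow, chance is therefore left undecided for these as recorded. The real split was also the only 1 of 35 as large for iron against immature (170, 0), iron against foot muscle (633, 0) and calcium against foot muscle (313, 106). There the replicate numbers pair the arrays, and the 8 splits that part all 4 pairs are too few for a share under 0.05; the 7 others of these called 0 probes in each, and the 106 came from a split that keeps pairs together. For calcium against immature the real count was 0, so that each of the 35 splits is as large by construction and the splits say nothing about chance. The highest, 622, came from setting immature 1 and 3 with calcium 2 and 4 against the rest, which points to a structure of the samples and is the value table's assignment. Of 100 drawn splits, 1 gave as many calls as the radula mean (597, highest other 36), and so did 1 of 100 drawn within replicate numbers (highest other 503), and chance can be excluded. For the F-test among sections (159), 2 of 100 splits drawn freely gave as many (highest other 161) but 16 of 100 drawn within replicate numbers (highest other 740, the count of the value table's assignment), so that chance is left undecided as recorded.

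For the value table's assignment, 1 of 35 splits, the real one, gave a count as large in each pair of tissues. For calcium against immature (622 calls, highest other 0), the numbers missed the required minimum under both assignments. They pair each of these tissues with iron, however, so a pairing between them cannot be excluded. The 8 splits that would then part all pairs have a lowest possible share of 0.125, and chance is left undecided. It is left undecided too for calcium against foot muscle (511, 0), because the numbers pair these tissues with the files as recorded (r 0.111 to 0.328). The numbers pair the arrays in iron against immature (511, 1), calcium against iron (521, 178), immature against foot muscle (759, 0) and iron against foot muscle (847, 0), where the 8 splits that part all pairs are again too few and the 7 others of these called 0. For the radula mean (860, highest other 266) and the F-test (740, 400), 1 of 100 drawn splits was as large in each, as was 1 of 100 drawn within replicate numbers (highest others 500 and 400), and chance can be excluded.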

How the results depend on the processing

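All fits with the value table's assignment or without the 4 disputed arrays were chosen after seeing the data. The 4 probes named for calcium against immature on the value table's assignment changed sign and lost their call with the files as recorded, at -0.0754 for Contig[0288], -0.0936 for PlateD-E11-5-SMART, 0.252 for Contig[0010] and 0.167 for Contig[0054]. Apart from these, 825 values of named probes kept their call, 35 lost it and none changed sign. Contig[0129] lost it for iron against immature without immature 1 or 3, any 1 iron or foot muscle array or calcium 1 (-1.58 to -1.23), with no background correction, median or loess scaling, either block, or only the tissues compared. Contig[0110] lost it for calcium against iron without any 1 iron array, calcium 2 or 4 or foot muscle 2 or 4 (1.21 to 1.47), with no background correction, loess, the value table or either block. Contig[0222] lost it for calcium against foot muscle without calcium 2 (-3.53) or 4 (-3.47) and under median scaling (-3.59), and Contig[0097] lost both calls under loess (-1.575 for iron against immature and 1.62 for calcium against iron). The cause was not tested. With no background measured, signal over background limits dim probes to an unknown degree.

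Counts as recorded moved by more than 1.5 times as follows, and the cause was not tested unless given. Files assigned as in the value table gave 511 for iron against immature (170), 622 for calcium against immature (0), 521 for calcium against iron (172), 759 for immature against foot muscle (301), 511 for calcium against foot muscle (313) and 740 for the F-test (159). Without the 4 disputed arrays the counts were 431, 429, 389 and 648 for the first 4 and 592 for the F-test. In both, the spread within immature and calcium fell. Against foot muscle, median scaling gave 154 for immature and 171 for calcium. Loess gave 152, 404, 169 and 336 for immature, iron, calcium and the radula mean. The 75th percentile gave 1444, 767 and 1306 for iron, calcium and the mean. Log2 of the value table, which has its own assignment and no background correction, gave 386, 503, 331 and 579 for iron against immature, calcium against immature, calcium against iron and the F-test, and 368, 193 and 358 for iron, calcium and the mean against foot muscle. Array weights gave 528 for calcium against iron, 802 for calcium against foot muscle and 448 for the F-test.

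With the replicate number as a block, counts as recorded were 480 for immature and 492 for calcium against foot muscle, and the block moved no other count by over 1.5 times. Of 16 arrays, 7 correlated best with their own number as recorded and 13 with the value table's assignment. There, the block gave 811 for calcium against foot muscle (511).

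With the value table's assignment, calcium against foot muscle was 328 under median scaling and 193 with the value table's own values. Immature against foot muscle (759) was 493 under loess, 1350 under the 75th percentile and 397 with the table's values. Iron against foot muscle (847) was 549, 1756 and 368. The radula mean (860) was 1607 under the 75th percentile and 358 with the table's values, and calcium against iron (521) was 331 with them.

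Leaving out 1 array at a time as recorded gave 122 to 199 calls for iron against immature, 0 for calcium against immature, 112 to 200 for calcium against iron, 99 to 185 for the F-test, and 220 to 369, 494 to 704, 238 to 314 and 484 to 623 for immature, iron, calcium and the mean against foot muscle. Without iron replicate 3, calcium against iron fell to 112 and the F-test to 99. With the value table's assignment the ranges were 478 to 524, 571 to 629, 449 to 534, 697 to 749, 687 to 795, 735 to 898, 437 to 539 and 766 to 855 in that order. The gene list tests were not run, no list having a member. The radula mean had no fit on only the tissues compared, since it uses all. Slides were not given, so only the sector, a position on a slide, could be used as a block, and an effect of the slide was not tested.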

Other observations

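Calls were also counted by sequence, over the probes each one carried. For iron-deposited against immature teeth, 40 sequences had at least 2 probes called higher and none lower as recorded, and 8 had at least 2 called lower and none higher. Among the undisputed arrays these counts were 59 and 48. For the radula mean against foot muscle, 52 sequences had at least 2 probes higher and 95 at least 2 lower as recorded, and 3 sequences had probes called in opposite directions. Between calcium-deposited and immature teeth, the undisputed arrays had 56 such sequences higher and 52 lower, and 0 with opposite calls.

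Under the value table's assignment, the 740 probes that differed among sections were spread over the radula, with 223 highest in immature teeth, 230 in iron-deposited and 287 in calcium-deposited teeth. Of the 223, 183 were called higher than foot muscle, as were 192 of the 230 and 94 of the 287, whereas 11, 9 and 56 were called lower. The calcium peak thus held the smallest share above foot muscle, a difference that was not tested. These counts use the same foot muscle arrays for each section.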
